A study of Homo sapiens with 9 samples.

How the data were processed

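Gene expression was measured in P493-6 cells, an established human B-lymphocyte line, on 9 single-colour Affymetrix arrays of 54675 probe sets. The labels place 4 arrays in a high Myc group, 3 in a low Myc group and 2 in a no Myc group, and give a replicate number for each. They state no treatment, time or culture, so it is not known whether the replicates came from separate cultures, and the p-values measure only the spread between these arrays, which may be technical. As background, this line is known for carrying a MYC gene that tetracycline switches off and a form of EBNA2, a transcription factor of Epstein-Barr virus, that needs estrogen. Total RNA was extracted with Qiagen RNeasy and labelled with biotin, per the labels' protocols.

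The values had been summarised per probe set by RMA, per the submitters' processing notes, and the version was not given in the sources used here. RMA subtracts background, gives the arrays a common distribution by quantile normalization and summarises the probes of each probe set on the log scale. The authors deposited these values as intensity on a linear scale, with array medians of 75.3 to 80.3, and log2 of the deposited intensity was used throughout. Because array distributions were made alike, a change in the total RNA per cell could not be seen, and each difference is relative to the other genes on the array. No detection calls were used here, so genes near the lowest intensities carry no statement on presence. A fold against a group read at a mean log2 under 5 is not exact, nor is its rank, and these cases are named beside the largest differences. The number of arrays limits the precision.

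Probe sets were named from the platform annotation. Of the 54675 probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had none, and only those with 1 symbol were named. The symbols of 41043 probe sets were brought up to date through the Entrez identifier. A gene with several probe sets was represented by the one with the highest mean log2 value over all 9 arrays, which gave 19775 genes, of which 10523 had more than 1 probe set. No genome build is named in the sources used here, and no coordinates are given.

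Group means were fitted with limma 3.58.1 in R 4.3.3 to the log2 values of all 9 arrays in 1 fit (lmFit, contrasts, eBayes without trend, 6 residual degrees of freedom), so that the groups shared 1 estimate of the spread. The tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The comparisons were high Myc with no Myc, low Myc with no Myc, and high Myc with low Myc. Genes called in the same direction against both other groups were counted as higher or lower in a group than in both others.

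Before the data were examined, 34 gene lists with 823 entries were fixed, of which 743 were measured. They covered MYC-linked processes, B-cell programmes, the Notch pathway and markers of other cell types, and were not chosen on these samples. The list of EBNA2-linked and B-cell activation genes is shortened below to EBNA2-linked genes. It also holds genes of B-cell activation in general, so a change in it is not specific to EBNA2. Lists were tested with camera at a preset inter-gene correlation of 0.01, with a correlation estimated per list, and with fry, and adjusted over the 34 lists of a comparison. Genes named in the text followed a rule fixed at the same time. It took MYC, MAX and called members of the MYC network, JAG2 and called Notch pathway genes. JAG2 was included because the study was already known for it, so its difference is no independent find. The rule also took, per comparison, the 8 called genes with the largest positive and the 8 with the largest negative log2 difference whose group values did not overlap, and up to 4 called members per list. Any gene named outside that rule is said to be so.

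The procedure was tested on 20 simulated sets of 19775 genes with 200 changed genes. In the design of high against no Myc it recovered 70.4% of 2-fold and 96.4% of 4-fold changes. The values were 64.4% and 94.2% for low against no Myc, and 77.3% and 96.5% for high against low Myc. False calls made up 5.04%, 5.33% and 5.19% of the calls. A changed list was called in 20 of the 20 sets in each comparison, and an unchanged list in 0, 2 and 0. The genes were simulated independently, so these sets do not test camera, or the share of false calls, where genes vary together. In the measured lists the estimated correlation reached 0.78, for chaperones.

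The alternatives were quantile normalization repeated on the deposited values, arrays centred on their median, a filter at a mean log2 of 5 that left 17241 genes, the median of a gene's probe sets, a trended and robust prior, array weights, only the 2 groups compared, the replicate number as a block, stricter thresholds, and each array left out in turn. Leaving out 2 doubted libraries together, and array sets as a block, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.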

Results

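RNA of P493-6 cells, a human B-lymphocyte line in which the level of the transcription factor MYC can be set, was measured on 9 arrays. The labels name 4 arrays high Myc, 3 low Myc and 2 no Myc, and the design asks how expression differs between the 3 levels. Median intensities were 75.3 to 80.3 per array. Correlations between arrays across the 19775 genes were 0.976 to 0.992 within groups and 0.917 to 0.982 between groups. The GAPDH signal near the 3' end exceeded that near the 5' end by 0.25 and 0.42 (log2) on the arrays labelled no Myc replicates 1 and 2, and by 0.01 to 0.24 on the 7 other arrays.

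MYC (Entrez gene 4609) was far higher on every high Myc array than elsewhere. Its intensity was 11326 to 15404 on the 4 high Myc arrays and 1443 to 2526 on the 3 low Myc arrays. The library labelled no Myc replicate 1 had 2803, above every low Myc array, and no Myc replicate 2 had 416. MYC was 3.57 ± 0.60 (log2 ± SE) higher in high Myc (13.65 ± 0.19, SD, n = 4) than in no Myc (10.08 ± 1.95, SD, n = 2), or 11.9-fold, with adjusted p = 0.00252. The difference was 4.95 without the library labelled no Myc replicate 1 and 2.19 without no Myc replicate 2. High Myc exceeded low Myc (10.95 ± 0.41, SD, n = 3) by 2.70 ± 0.53, or 6.49-fold (adjusted p = 0.0321). That call was lost on leaving out high Myc replicate 1, 3 or 4 or low Myc replicate 1 or 3, with differences of 2.70, 2.61, 2.72, 2.75 and 2.47 and adjusted p of 0.0827, 0.0988, 0.0864, 0.0982 and 0.0899. These fits kept both no Myc arrays, whose spread in MYC enters the shared estimate. With only the high and low Myc arrays fitted, the difference was again 2.70, with adjusted p = 0.00246. Low Myc and no Myc differed by 0.87 ± 0.64 (adjusted p = 0.484). Without the library labelled no Myc replicate 1 that difference was 2.25 and called (adjusted p = 0.00842), and without no Myc replicate 2 it was -0.50 and not called. Every direction drawn below from the no Myc group includes this library, whose MYC level went against its label.

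JAG2, a ligand of Notch receptors, was high on the 4 high Myc arrays and low on the 5 others. JAG2 (Entrez gene 3714) read 972 to 1223 on the high Myc arrays, 178 to 300 on the low Myc arrays and 185 to 255 on the arrays labelled no Myc. JAG2 was 5.18-fold higher in high Myc than in no Myc (log2 2.37 ± 0.21, adjusted p = 0.000163) and 4.85-fold higher than in low Myc (2.28 ± 0.19, adjusted p = 0.00103). Low Myc and no Myc differed by 0.09 ± 0.22 (adjusted p = 0.892). A second JAG2 probe set read 936 to 1188, 167 to 324 and 208 to 217 in the same groups. MAX, the partner with which MYC binds DNA, differed by -0.08 ± 0.17 between high Myc and no Myc (adjusted p = 0.847).

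**Figure D1:**
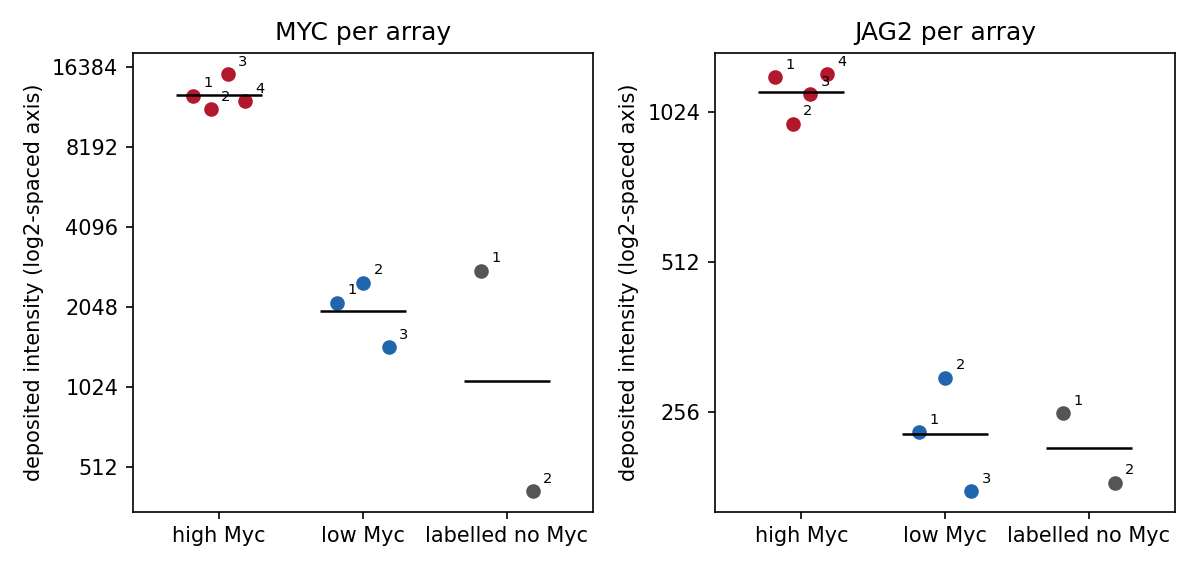
Deposited intensity of MYC and JAG2 on each of the 9 arrays, on a log2-spaced axis, with replicate numbers beside the points and lines at the mean of the log2 values. The 4 high Myc arrays lie at 11326 to 15404 for MYC and at 972 to 1223 for JAG2, and the library labelled no Myc replicate 1 lies at 2803 for MYC, above all low Myc arrays.

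High Myc cells expressed far more of the machinery for growth and division than the no Myc group. The largest rises were KISS1R, the kisspeptin receptor (41.7-fold), PSAT1, an enzyme of serine synthesis (18.3-fold), GAL, the neuropeptide galanin (log2 4.17 ± 0.36), and LIN28B, an RNA-binding protein that blocks let-7 maturation (17.0-fold, not called without no Myc replicate 2, adjusted p = 0.056). PEG10, an imprinted gene derived from a retrotransposon (16.8-fold), ZC3HAV1L (15.1-fold), PUS7, a pseudouridine synthase (14.4-fold), and FABP5, a fatty acid-binding protein (13.7-fold), followed. The fold of LIN28B is not exact, as no Myc read 4.53 (mean log2). Of 39 measured genes of nucleolar ribosome biogenesis, 38 rose (38 adjusted over the list alone), with a median log2 difference of 1.93. They were led by POLR3G of RNA polymerase III (3.40 ± 0.52), LYAR (3.24 ± 0.45), POLR1B of RNA polymerase I (3.08 ± 0.26) and NOP16 (2.85 ± 0.25). The difference of POLR3G and its rank are not exact, as no Myc read 4.85 (mean log2). All 22 genes of nucleotide synthesis rose (22 adjusted over the list alone, median 1.62), including the purine enzymes PFAS (7.77-fold), PAICS (7.45-fold) and PPAT (6.03-fold).

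Replication, mitosis and mitochondrial genes rose with them. In the same comparison 29 of 34 DNA replication genes rose (33 adjusted over the list alone), such as CDC6, which loads the replicative helicase (6.59-fold), and 31 of 33 mitosis genes (32 adjusted over the list alone), such as MAD2L1 of the spindle checkpoint (5.54-fold). In the mitochondria, 29 of 30 ribosomal proteins rose (30 adjusted over the list alone), with MRPS2 at 5.71-fold, as did 25 of 32 genes of oxidative phosphorylation (29 adjusted over the list alone), with cytochrome c, CYCS, at 3.75-fold. Risers among chaperones were 19 of 20, among aminoacyl-tRNA synthetases 15 of 17 and among translation factors 15 of 19 (19, 15 and 17 adjusted over the list alone). Serine and one-carbon metabolism had 10 of 12 (10 adjusted over the list alone). The list of polyamines, glutamine and amino acid transport had 13 of 20 risers, led by the transporter subunit SLC7A5 (10.7-fold), and 1 faller, the polyamine-acetylating enzyme SAT1 at -2.54 (13 and 1 adjusted over the list alone). SAT1 was not called without high Myc replicate 1, 3 or 4 or the library labelled no Myc replicate 1. Glycolysis had 13 of 20 risers, with GPI at 5.13-fold, and 2 fallers, SLC2A3 (-1.08) and ALDOC (-1.03), which were 1 without high Myc replicate 3 or either no Myc array (13 and 3 adjusted over the list alone). SAT1, SLC2A3 and ALDOC were named after their values were seen. Of 39 cytosolic ribosomal proteins, 2 rose, RPL14 (0.55 ± 0.10) and RPL3 (0.30 ± 0.10), and 1 when adjusted over the list alone. The median was 0.08, and the list was not called by camera (adjusted p = 0.0643) and called upward by fry (adjusted p = 0.0253), with adjusted p = 0.623 with an estimated correlation. RPL14 was not called without the library labelled no Myc replicate 1 (adjusted p = 0.0567), and RPL3 was called in 1 of the 9 fits that left out 1 array, that without no Myc replicate 2, with an adjusted p of up to 0.399 in the others. In the MYC network, MXI1, a MAX partner that opposes MYC, rose besides MYC (1.76 ± 0.33). MXI1 was not called without no Myc replicate 2 (adjusted p = 0.0516).

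Genes of the interferon response and of antigen presentation were lower in high Myc than in no Myc. The largest falls were IFI27 (26.9-fold lower), IFI44 (21.4-fold), IFI44L (19.5-fold), DDX60 (18.5-fold), SAMD9L (17.0-fold) and IFIT1 (16.2-fold), all known as interferon-induced, then LYZ, lysozyme (14.4-fold), and CCR2, a chemokine receptor (log2 -3.58 ± 0.60). The fold of DDX60 is not exact, as high Myc read 4.29 (mean log2), nor is that of LYZ, read under 5 on 2 high Myc arrays. IFI44L was not called without the library labelled no Myc replicate 1 (adjusted p = 0.075). Of 26 interferon-stimulated genes, 24 fell (25 adjusted over the list alone), with a median log2 difference of -2.34. Between the arrays labelled no Myc, all 26 were higher in replicate 1, by a median of 0.94, and 19 fell when that library was left out. All 13 genes of MHC class II presentation fell (13 adjusted over the list alone, median -1.55), among them HLA-DOB (-2.61 ± 0.26) and HLA-DOA (-2.30 ± 0.14), which modulate peptide loading. In MHC class I presentation, 13 of 17 fell, such as HLA-E (-1.78 ± 0.14), and CALR, a chaperone of the endoplasmic reticulum named after its value was seen, rose by 0.44 (13 and 1 adjusted over the list alone). CALR was not called without high Myc replicate 2 or 4 or either no Myc array.

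B-cell identity genes fell in 16 of 23 cases (18 adjusted over the list alone, median -1.26), among them VPREB3, a pre-B-cell gene (11.6-fold lower), the inhibitory receptor CD72 (11.5-fold) and the tetraspanin CD37 (6.63-fold). That count was 6 without the library labelled no Myc replicate 1. In the list of EBNA2-linked and B-cell activation genes 10 of 33 fell (12 adjusted over the list alone, median -0.95), led by FCER2, the low-affinity IgE receptor (-1.78 ± 0.25), and this count was 23 without high Myc replicate 2, 2 without the library labelled no Myc replicate 1 and 4 without no Myc replicate 2. BTG1, an antiproliferative gene, was 3.97-fold lower and MCL1, a survival factor, 2.52-fold lower. Among BCL2 family and apoptosis genes 6 of 18 fell and BCL2L11 rose by 0.93 (8 and 1 adjusted over the list alone). The fallers were 3 without high Myc replicate 1 or 3, low Myc replicate 1 or no Myc replicate 2, and 2 without the library labelled no Myc replicate 1. For adhesion and cytoskeleton genes, 5 of 28 fell, led by the integrin ITGAM (8.26-fold lower), and ACTN1 rose by 1.40 (6 and 1 adjusted over the list alone). Without no Myc replicate 2 the fallers were 3, and ACTN1 was not called without either no Myc array. Lysosome and autophagy genes fell in 9 of 25 cases, such as TFEB (-1.59 ± 0.17), and CTSC, GAA and GLA rose (10 and 4 adjusted over the list alone). The risers were 1 without either no Myc array. Of 17 germinal-centre B-cell genes, CD27 (-1.34 ± 0.25) and LMO2 (-1.29 ± 0.15) fell (2 adjusted over the list alone). BCL2L11, GAA and GLA were named after their values were seen.

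In the Notch pathway list, JAG2, MFNG (1.62 ± 0.28) and NRARP (1.53 ± 0.44) of 26 genes were higher in high Myc than in no Myc, and NUMB (-1.27 ± 0.19), MAML2 (-1.19 ± 0.21) and LFNG (-0.60 ± 0.11) were lower (3 and 3 adjusted over the list alone). NRARP was not called without high Myc replicate 3 or either no Myc array, with an adjusted p of up to 0.185. The list was called neither by camera (adjusted p = 0.855, median 0.02, mean 0.08, test direction down) nor by fry (0.848). In G1 cell cycle genes 8 of 23 rose, led by the phosphatase CDC25A (2.28 ± 0.27), and BTG1, CDKN2D and RBL2 fell (9 and 3 adjusted over the list alone). The risers were 4 without high Myc replicate 3, 3 without the library labelled no Myc replicate 1 and 4 without no Myc replicate 2. Cholesterol synthesis had 4 of 17 risers, DHCR7, EBP, NSDHL and LSS (4 adjusted over the list alone), of which 1 was called without no Myc replicate 2. In the hypoxia list BNIP3, VEGFA, MXI1 and ERO1A of 18 genes rose and P4HA2 and BNIP3L fell (5 and 3 adjusted over the list alone). Of 20 stress genes BAG3, HSPA5, TRIB3 and ATF4 rose and IER2 and JUNB fell (4 and 2 adjusted over the list alone, median 0.11, mean -0.05). The hypoxia risers were 2 without no Myc replicate 2, and the fallers 0 without the library labelled no Myc replicate 1 and 1 without no Myc or high Myc replicate 2. Stress risers were 2 and fallers 4 without no Myc replicate 2, and fallers 1 without the library labelled no Myc replicate 1. DLEU2, a microRNA host gene, fell by 1.47 on the log2 scale among 3 such genes (1 adjusted over the list alone) and was not called without high Myc replicate 3 or either no Myc array. CDKN2D, RBL2, P4HA2, BNIP3L, TRIB3 and ATF4 were named after their values were seen.

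Camera called no list of markers of other cell types, while fry called the myeloid list downward (adjusted p = 0.0175, and 0.383 with an estimated correlation). In the myeloid list LYZ and ITGAM of 17 genes fell (2 adjusted over the list alone, median -0.09, mean -0.47). In the T and NK cell list IL7R rose and CD2 fell of 23 genes (1 and 0 adjusted over the list alone), and in the plasma cell list FKBP11 and XBP1 of 14 rose (1 adjusted over the list alone). CD2 was not called in 6 of the 9 fits that left out 1 array and XBP1 not in 7, with adjusted p of up to 0.394 and 0.346. By limma 0 of 12 erythroid and platelet genes and 0 of 20 fibroblast and epithelial genes passed (0 and 0 adjusted over the list alone), with 0 and 1 at an unadjusted p under 0.05, and the latter list had a median of -0.07, a mean of 0.01 and a test direction of down. None of these lists was called by camera, nor were G1 cell cycle, cholesterol, hypoxia, stress, microRNA host and MYC network genes, while fry called the myeloid, G1, MYC network, microRNA host and cytosolic ribosomal protein lists, with adjusted p of 0.383 to 0.623 with an estimated correlation.

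High Myc and no Myc differed at 4584 of 19775 genes (23.2%), of which 2805 were higher and 1779 lower in high Myc, and 2230 differed at least 2-fold. Camera called 21 of the 34 lists, 12 up and 9 down, and fry called 26, with 21 in common. No list was called with an estimated correlation, where the adjusted p of the 21 lists lay between 0.168 and 0.383 and 9 lists had an unadjusted p under 0.05. For EBNA2-linked genes this was adjusted p = 0.383 with an estimated correlation, and for nucleolar ribosome biogenesis adjusted p = 0.168 with an estimated correlation. Without the library labelled no Myc replicate 1, which rested the no Myc group on 1 array assumed to vary like the others, 2714 genes were called, 2678 of them shared. The camera call was lost for the BCL2 family without high Myc replicate 1 or 4, low Myc replicate 2 or the library labelled no Myc replicate 1 (adjusted p up to 0.122), for germinal-centre genes without high or no Myc replicate 2 (up to 0.23) and for lysosome genes without high Myc replicate 1 (0.0604). Cholesterol synthesis was called without low Myc replicate 1 or the library labelled no Myc replicate 1 (down to 0.0308). The GAPDH difference between the 3' and 5' ends, 0.25 and 0.42 on the no Myc arrays against at most 0.24 on the others, was higher in the no Myc group that all these lists were set against. The same difference for ACTB was 0.00 and -0.01 on the no Myc arrays and -0.07 to 0.19 on the others.

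**Figure D2:**
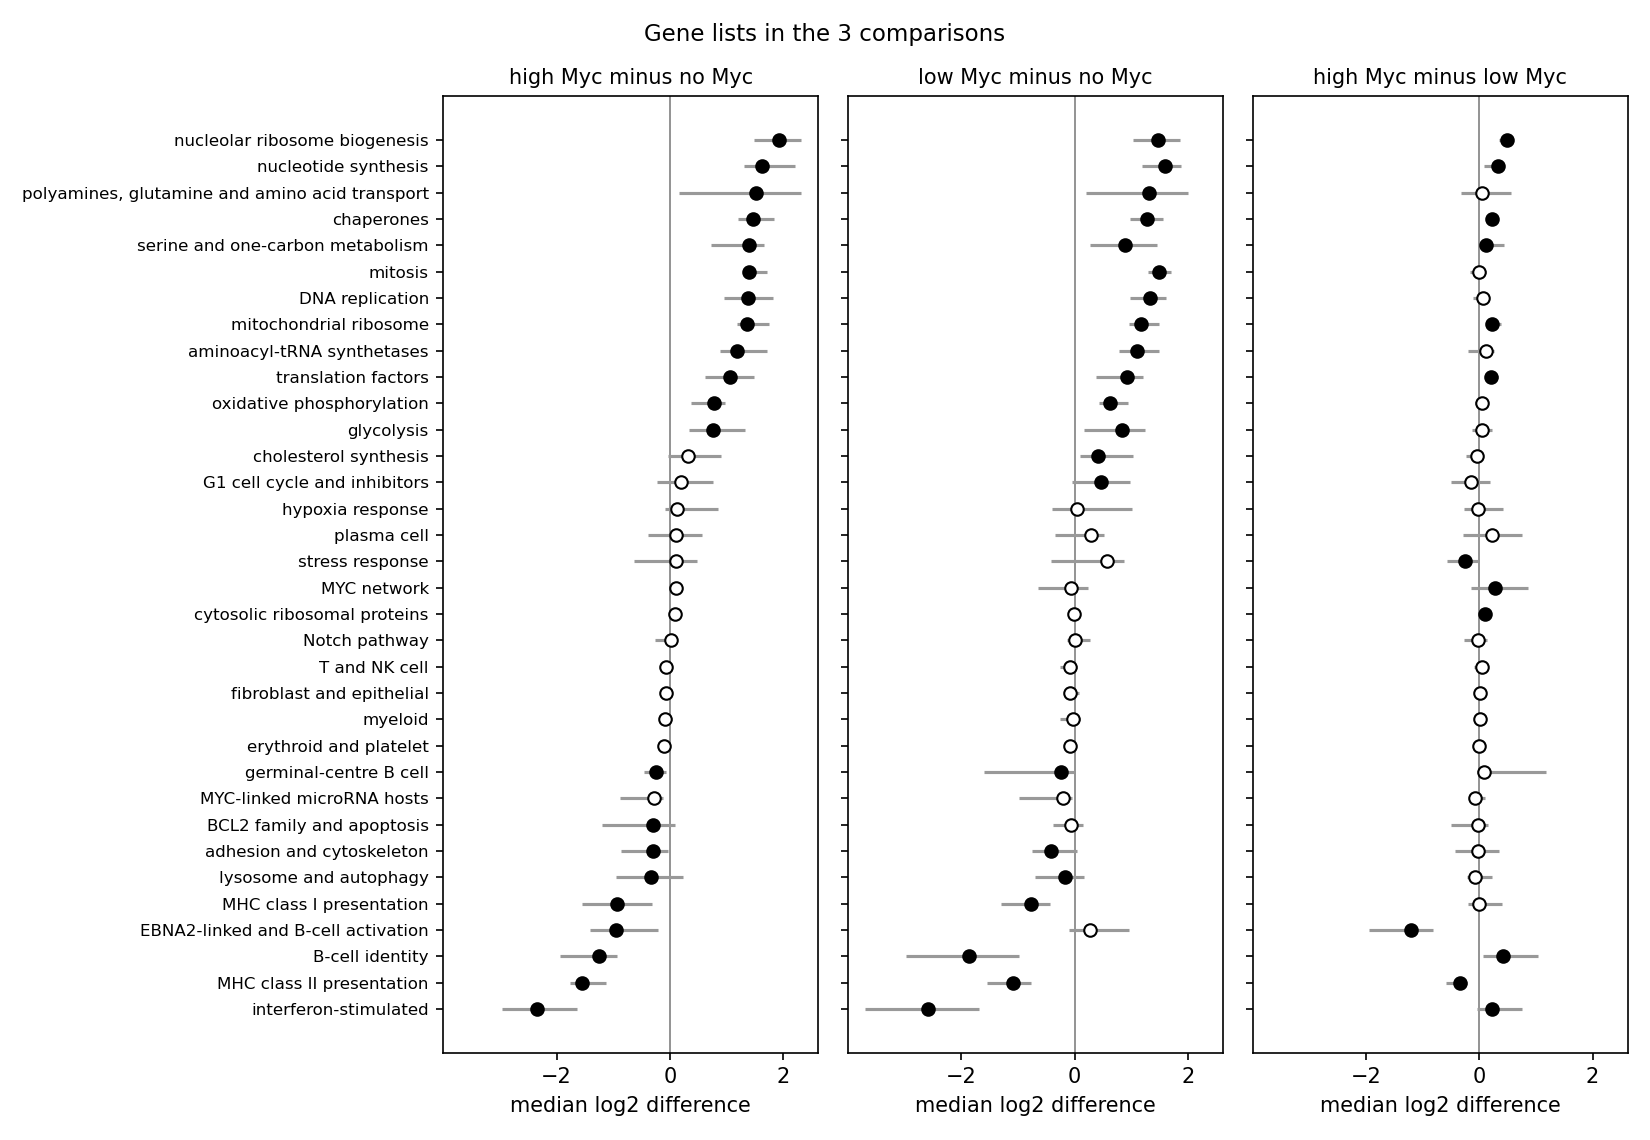
Median log2 difference of each of the 34 gene lists in the 3 comparisons, with bars from the lower to the upper quartile of the members and filled points where camera with a preset correlation called the list. The median of nucleolar ribosome biogenesis lies at 1.93, 1.47 and 0.50 for high against no Myc, low against no Myc and high against low Myc, and that of interferon-stimulated genes at -2.34, -2.59 and 0.22.

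Low Myc cells differed from the no Myc group in genes of growth and division, of the interferon response and of B-cell identity. PSAT1 was 17.8-fold higher, OTP, a homeobox gene, 16.2-fold and ZC3H12C 14.1-fold. Larger still were IL1R2, a decoy receptor of interleukin 1 (38.1-fold), PPEF1 (26.9-fold), ADAMDEC1 (26.8-fold) and ACKR3, a chemokine receptor (19.3-fold), followed by CDK5R1 (13.7-fold). These 5 were not called when either no Myc array or, depending on the gene, 1 to 6 other arrays were left out, with an adjusted p of up to 0.131, 0.19, 0.141, 0.145 and 0.145. The largest falls were OSBPL10 (87.7-fold lower), the lipoxygenase ALOX5 (86.6-fold), TBC1D9 (62.6-fold), IFI44L (51.5-fold), VPREB3 (49.5-fold), GAPT (38.1-fold), IFI27 (33.9-fold) and IFIT1 (33.5-fold). These folds and their order are not exact for ZC3H12C, ADAMDEC1 and OTP, read at a mean log2 of 4.06, 4.29 and 4.85 in no Myc, and for OSBPL10, read at 4.52 in low Myc. The same holds for ALOX5 and GAPT, read under 5 on 1 low Myc array each, and CDK5R1, on 1 no Myc array. Of the proliferation genes, 32 of 33 mitosis genes rose (33 adjusted over the list alone, median 1.49), such as cyclin B1, CCNB1 (3.74-fold), and 30 of 34 DNA replication genes (34 adjusted over the list alone), with CDC6 at 6.00-fold. Nucleolar ribosome biogenesis rose in 37 of 39 (38 adjusted over the list alone), with POLR1B at 4.95-fold, and nucleotide synthesis in 21 of 22 (22 adjusted over the list alone), with PAICS at 5.83-fold.

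In the same comparison mitochondrial ribosomal proteins rose in 28 of 30 cases, oxidative phosphorylation genes in 24 of 32, chaperones in 18 of 20, aminoacyl-tRNA synthetases in 16 of 17 and translation factors in 11 of 19 (29, 28, 19, 17 and 14 adjusted over the list alone). Without the library labelled no Myc replicate 1 the counts of the last 2 were 9 and 6, and translation factors had 7 without no Myc replicate 2. Polyamine, glutamine and amino acid transport genes rose in 13 of 20 cases, with SLC7A1 at 7.80-fold, glycolysis genes in 12 of 20, and serine and one-carbon genes in 6 of 12 (14, 13 and 8 higher and 1, 1 and 0 lower adjusted over the list alone). Among G1 genes 10 of 23 rose and RB1, BTG1 and CDKN2D fell (10 and 3 adjusted over the list alone), where the risers were 6 without low Myc replicate 1 or 2 or no Myc replicate 2 and 4 without the library labelled no Myc replicate 1, which left 1 faller. Cholesterol synthesis had 6 of 17 risers (8 adjusted over the list alone), 2 without the library labelled no Myc replicate 1 and 1 without no Myc replicate 2. CDKN2D was named after its value was seen.

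Interferon-stimulated genes fell in 23 of 26 cases between low and no Myc (24 adjusted over the list alone, median -2.59), and in 20 without the library labelled no Myc replicate 1, in which all 26 were higher than in no Myc replicate 2. B-cell identity genes fell in 17 of 23 (20 adjusted over the list alone), among them CD72 (29.0-fold lower) and FCRL2 (13.3-fold). MHC class II genes fell in 12 of 13 (13 adjusted over the list alone), such as CIITA, the activator of this gene family (3.75-fold), and MHC class I genes in 13 of 17, such as the peptide transporter TAP2 (3.89-fold), with CALR higher by 0.44 (14 and 1 adjusted over the list alone). Without the library labelled no Myc replicate 1 these 3 counts were 8, 7 and 7. CALR, named after its value was seen, was not called without 6 of the arrays. Germinal-centre genes fell in 6 of 17, such as CD27 (6.95-fold), and GCSAM rose (6 and 1 adjusted over the list alone). The fallers were 3 without low Myc replicate 1 or either no Myc array, and GCSAM was not called without either no Myc array. Adhesion genes fell in 6 of 28, led by ITGAM (10.5-fold), and ACTN1, LIMA1 and TPM4 rose (7 and 3 adjusted over the list alone). Lysosome genes fell in 6 of 25, such as CTSB (-1.68 ± 0.10), and CTSC rose (8 and 2 adjusted over the list alone), with 2 and 3 risers without high Myc replicate 2 and low Myc replicate 3. Both of these counts of fallers were 3 without the library labelled no Myc replicate 1, and the 3 adhesion risers were 0 without low Myc replicate 1 or either no Myc array. LIMA1 and TPM4 were named after their values were seen.

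Lists without a camera call between low and no Myc included EBNA2-linked genes (adjusted p = 0.168, 0.763 with an estimated correlation and 0.434 by fry), of which CDK5R1, CR2, BATF, CD80 and STAT5A rose and FGR and TNF fell of 33 (6 and 2 adjusted over the list alone). The risers were 9 without high Myc replicate 2, 1 without low Myc replicate 1 or the library labelled no Myc replicate 1, 3 without low Myc replicate 2 and 2 without no Myc replicate 2, and the fallers were 0 or 1 in 7 of the 9 fits. In the Notch pathway NOTCH1 (1.15 ± 0.30) and DTX1 (1.13 ± 0.23) rose and ADAM17 (-1.04 ± 0.14), LFNG (-1.01 ± 0.12) and NUMB (-0.95 ± 0.20) fell (3 and 3 adjusted over the list alone), and NOTCH1 and DTX1 were not called without either no Myc array, nor NUMB without the library labelled no Myc replicate 1. Fry called 2 of the lists that camera did not, the MYC network (adjusted p = 0.039) and the myeloid list (0.016), which were not called with an estimated correlation (0.473 for both). The MYC network genes MLXIP (-0.91 ± 0.15) and MAX (-0.63 ± 0.18) fell (3 adjusted over the list alone), and MAX was not called in 7 of the 9 fits that left out 1 array, with an adjusted p of up to 0.301. In the BCL2 family BIK (13.1-fold lower), MCL1 and CASP8 fell (3 adjusted over the list alone), and CASP8 was not called in 6 of the 9 fits that left out 1 array (adjusted p up to 0.306). In the hypoxia list EGLN1, ERO1A, DDIT4 and BNIP3 rose and KDM3A fell (4 and 1 adjusted over the list alone). In the stress list BAG3, CHAC1, TRIB3, HSPA5 and ATF4 rose and IER2 fell (6 and 1 adjusted over the list alone). The hypoxia risers were 2 without either no Myc array, the hypoxia fallers 0 without the library labelled no Myc replicate 1 and 2 without low Myc replicate 3, and the stress risers 9, 2, 1 and 0 without high Myc replicate 2, low Myc replicate 1 and no Myc replicates 1 and 2. The stress fallers were 3 without no Myc replicate 2. LYZ and ITGAM of the myeloid list, ZAP70 of the T and NK cell list, JCHAIN of the plasma cell list and DLEU2 fell, and SEC11C of the plasma cell list and CDH1 of the epithelial list rose (2, 0, 1, 1, 0 and 1 in these lists when adjusted over the list alone). Besides LYZ and ITGAM these were not called without either no Myc array. The plasma cell list had a median of 0.29 and a mean of -0.15, and the fibroblast and epithelial list a median of -0.08 and a mean of 0.11. By limma 0 cytosolic ribosomal proteins of 39 and 0 erythroid and platelet genes of 12 passed (0 and 0 adjusted over the list alone), with 2 and 0 at an unadjusted p under 0.05. STAT5A, FGR, TNF, KDM3A, HSPA5 and ATF4 were named after their values were seen.

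Low Myc and no Myc differed at 3919 genes (19.8%), 2228 higher and 1691 lower in low Myc, of which 1913 differed at least 2-fold. Camera called 21 lists, 14 up and 7 down, and fry 22, with 20 in common. With an estimated correlation no list was called, 9 had an unadjusted p under 0.05, and the adjusted p of the 21 lay between 0.147 and 0.559, the last for cholesterol synthesis. The camera call was lost for cholesterol synthesis without low Myc replicate 1 or no Myc replicate 2 (adjusted p up to 0.101) and for lysosome genes without low Myc replicate 3 (0.187). EBNA2-linked genes were called without high Myc replicate 2 (0.0174), and stress genes without that array (0.0368) or the library labelled no Myc replicate 1 (0.00857). Leaving out the library labelled no Myc replicate 1 left 1855 genes called, 1831 of them shared.

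High Myc and low Myc, the comparison with the most arrays, differed at far fewer genes. RGCC, a regulator of the cell cycle (20.5-fold), GAL (11.9-fold) and KANK1 (8.92-fold) were higher in high Myc, and TIMP1, a metalloproteinase inhibitor (log2 -4.17 ± 0.48), HNRNPLL, a splicing regulator of lymphocytes (13.6-fold), RCAN3 (10.5-fold) and CR2, a complement receptor of B cells (10.4-fold), were lower. These 7 genes were called in all 9 fits that left out 1 array. JCHAIN, the joining chain of immunoglobulins (21.2-fold), OSBPL10 (15.6-fold), KISS1R (14.3-fold), ALOX5 (13.7-fold) and NEFH, a neurofilament (10.6-fold), were higher, and CDK5R1 (14.6-fold), XCL1 (12.3-fold), OTP (12.1-fold) and ZC3H12C (10.2-fold) lower. KISS1R was not called without low Myc replicate 1 (adjusted p = 0.0504), ALOX5 without that array or high Myc replicate 4 (up to 0.0519), and the other 7 without 4 to 8 of the 9 arrays, with an adjusted p of up to 0.144. The folds are not exact for OSBPL10 (mean log2 of 4.52 in low Myc), ZC3H12C and HNRNPLL (4.53 and 4.71 in high Myc), nor for CDK5R1, RCAN3 and OTP, read under 5 on 3 high Myc arrays, and ALOX5, on 1 low Myc array. In the MYC network MXI1 (2.78 ± 0.29), MYC, MLXIP (0.94 ± 0.12), MNT (0.84 ± 0.18) and MGA (0.52 ± 0.10) were higher in high Myc (6 higher and 1 lower adjusted over the list alone), and 2 or 3 genes of the list were higher in 7 of the 9 fits that left out 1 array. MAX differed by 0.55 ± 0.15 (adjusted p = 0.0873). In the Notch pathway JAG2, MFNG (1.21 ± 0.25) and ADAM17 (0.64 ± 0.12) were higher and NOTCH2 (-1.86 ± 0.36) and MAML2 (-1.03 ± 0.18) lower (4 and 4 adjusted over the list alone), and all but JAG2 lost the call without 4 to 7 of the arrays.

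Genes called numbered 712 (3.60%), 460 higher and 252 lower in high Myc, of which 328 differed at least 2-fold and 3253 genes had an unadjusted p under 0.05. The share of higher genes was 64.6%, 51.3% with quantile normalization repeated, 50.1% with the 2 doubted libraries left out, and 51.2% to 81.5% with 1 array left out. The count was 1204 without high Myc replicate 2 (616 higher, 588 lower), and 283, 254, 228 and 238 without high Myc replicates 1, 3 and 4 and low Myc replicate 1 (205, 176, 168 and 194 higher, 78, 78, 60 and 44 lower). Without low Myc replicate 3 the higher genes were 279. The count was 406 without either no Myc array (285 higher, 121 lower), since those arrays add to the shared estimate of the spread.

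EBNA2-linked and B-cell activation genes were lower in high Myc than in low Myc as a list by camera (adjusted p = 1.98e-21), but were not called with an estimated correlation (adjusted p = 0.523) or by fry (0.0556). Of 33 genes 8 fell (30 adjusted over the list alone), with a median log2 difference of -1.20, among them CDK5R1, CR2 (-3.38 ± 0.41), SLAMF1 (-2.76 ± 0.58) and CD80 (-2.20 ± 0.41), the latter pair known as lymphocyte surface proteins. The mean log2 of the list was 8.29, 9.68, 8.86 and 8.37 on high Myc replicates 1 to 4 and 10.31, 10.22 and 10.09 on low Myc replicates 1 to 3. The count was 24 without high Myc replicate 2, 2 without high Myc replicate 1, 3 or 4 or low Myc replicate 1, 5 without low Myc replicate 2 and 4 without either no Myc array. MHC class II genes fell in 3 of 13 cases (6 lower and 1 higher adjusted over the list alone), HLA-DMB (-0.86 ± 0.17), HLA-DOA (-0.76 ± 0.12) and HLA-DQB1 (-0.72 ± 0.15), with camera at 7.3e-05, adjusted p = 0.862 with an estimated correlation and 0.142 by fry. Without high Myc replicate 4 these were 0, and 1 without high Myc replicate 1, low Myc replicate 1 or 2 or either no Myc array.

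By camera, some biosynthesis lists lay higher in high Myc than in low Myc, with few single genes called and no call of these lists with an estimated correlation or by fry. Camera did not call aminoacyl-tRNA synthetases (adjusted p = 0.698), the amino acid transport list (0.115) or cholesterol synthesis (0.242, test direction down). By limma 0 of 39 nucleolar ribosome biogenesis genes passed (14 adjusted over the list alone), 24 were higher at an unadjusted p under 0.05 and the median was 0.50, with camera at 5.21e-13 and adjusted p = 0.862 with an estimated correlation. Without low Myc replicate 2, 7 passed. Of 39 cytosolic ribosomal proteins 0 passed (0 adjusted over the list alone), 6 were higher at an unadjusted p under 0.05 and the median was 0.10, with camera at 0.000471 and adjusted p = 0.862 with an estimated correlation. In the mitochondrial ribosome MRPS2 rose by 1.11 ± 0.11 (7 adjusted over the list alone, median 0.23), and the camera call was lost without low Myc replicate 3 (adjusted p = 0.0554). Camera alone called, upward, the lists of translation factors, chaperones, nucleotide synthesis and serine and one-carbon metabolism (adjusted p of 0.862 to 0.96 with an estimated correlation and 0.142 to 0.548 by fry), with EIF4EBP1, DNAJC2, IMPDH1, and GLDC and AHCY as members that rose (4, 2, 1 and 3 adjusted over the list alone). It further called the MYC network (adjusted p = 0.0221, 0.523 with an estimated correlation and 0.00792 by fry) and, with no call by the 2 other tests (0.96 with an estimated correlation, 0.59 to 0.673 by fry), interferon-stimulated genes with ISG20 higher (2 adjusted over the list alone), and B-cell identity with SYK higher and CD22 lower (4 and 2 adjusted over the list alone). Camera called stress response genes downward (0.862 with an estimated correlation, 0.548 by fry), with 0 of 20 passing (0 adjusted over the list alone, 5 lower at an unadjusted p under 0.05). All of these members but MRPS2 and GLDC lost the call without 3 to 8 of the 9 arrays. Without high Myc replicate 2, 9 B-cell identity genes were higher and 4 stress genes lower. Leaving out 1 array kept the camera calls of EBNA2-linked, MHC class II, nucleolar and cytosolic ribosomal genes. Low Myc replicate 3 left out ended those of translation factors (adjusted p = 0.182), chaperones (0.383), nucleotide synthesis (0.313) and serine metabolism (0.132), and high Myc replicate 2 left out those of chaperones (0.0595) and serine metabolism (0.0662). The calls of the MYC network and stress genes ended without high Myc replicate 4 or low Myc replicate 1 (up to 0.0638 and 0.0653), of interferon-stimulated genes without high Myc replicate 1, 2 or 4 or low Myc replicate 2 (up to 0.296), and of B-cell identity without 6 of the arrays (up to 0.323). In total camera called 13 lists, 10 up and 3 down, fry called 1, the MYC network, and 0 were called with an estimated correlation (adjusted p from 0.523 to 0.96, 2 with an unadjusted p under 0.05).

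Of the 21 other lists, DNA replication, mitosis, oxidative phosphorylation, aminoacyl-tRNA synthetases, MHC class I presentation, myeloid, erythroid and platelet, fibroblast and epithelial, and microRNA host genes had 0 called members by limma between high and low Myc, with at most 4 higher and 2 lower at an unadjusted p under 0.05 in each, and 0 adjusted over the list alone except 1 higher and 1 lower in MHC class I. TCL1A, CD27 and BCL7A of 17 germinal-centre genes, SLC7A5 and SLC43A1 of the amino acid transport list, MXI1 and EGLN3 of the hypoxia list, JCHAIN of the plasma cell list, IL7R of the T and NK cell list, and ITGA4 and ANXA2 of the adhesion list were higher. Adjusted over the list alone these lists had 4, 6, 2, 3, 1 and 2 higher and 1, 1, 2, 2, 0 and 2 lower genes. Lower were CDK2 and CCND2 of the G1 list, BCL2L1 of the BCL2 family, SLC2A3 of glycolysis, TM7SF2 of cholesterol synthesis, TFEB of the lysosome list and TPM4 of the adhesion list (5, 4, 2, 1, 5 and 2 lower and 1, 2, 0, 0, 2 and 2 higher adjusted over the list alone). MXI1, IL7R and ANXA2 kept the call in all 9 fits that left out 1 array, and the others lost it without 1 to 8 of the arrays. Camera called DNA replication without low Myc replicate 2 (adjusted p = 0.0415), mitosis (0.0178) and cholesterol synthesis (2.89e-05) without low Myc replicate 3, the G1 list without high or low Myc replicate 3 (down to 0.0147) and the amino acid transport list without high Myc replicate 1 or 4 or low Myc replicate 2 (down to 0.0241). The median and the mean differed in sign for fibroblast and epithelial (0.02 and -0.10), adhesion (-0.02 and 0.05), glycolysis (0.05 and -0.05) and hypoxia genes (-0.02 and 0.09), and for MYC-linked microRNA hosts (-0.08 and 0.04), and the myeloid list had a positive median and mean (0.01 and 0.02) with a test direction of down.

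**Figure D3:**
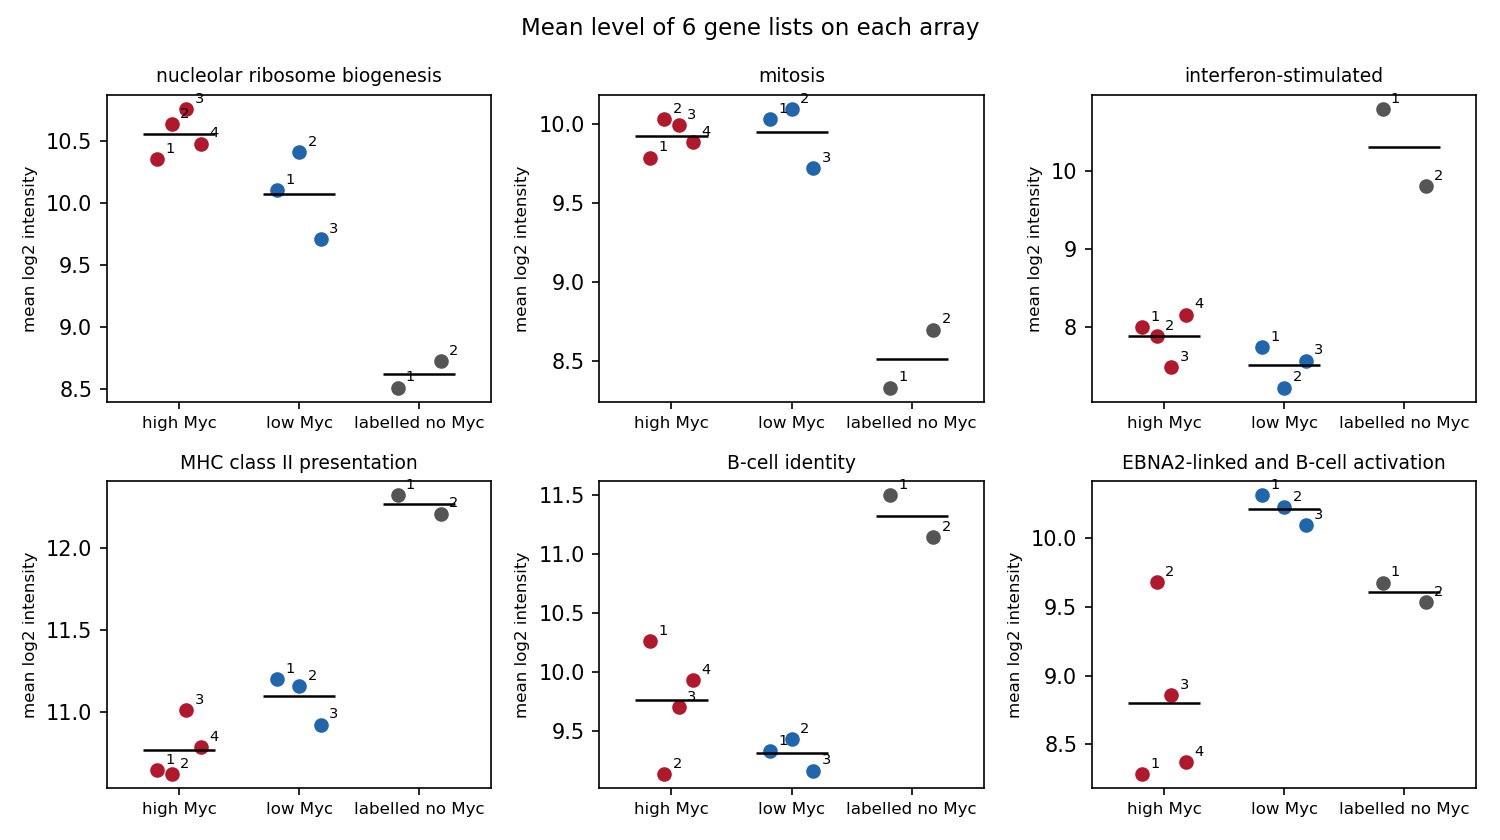
Mean log2 intensity of the members of 6 gene lists on each of the 9 arrays, with a line at the mean of each group. EBNA2-linked and B-cell activation genes lie at 10.09 to 10.31 on the low Myc arrays and at 8.29 to 9.68 on the high Myc arrays, where replicate 2 is the highest. They lie at 9.68 and 9.54 on the arrays labelled no Myc replicates 1 and 2.

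Genes set apart in high Myc from both other groups were led by KISS1R, GAL, NEFH, NPW, a neuropeptide (8.06-fold against the nearer group, not exact with a mean log2 of 4.52 and 4.18 in low and no Myc), MAP3K21 (6.94-fold), CSRP2 (6.71-fold) and MYC, with JAG2 (4.85-fold) among the first 12. In this class were 258 genes, and 110 were lower in high Myc than in both other groups, led by RASGRP1 (3.76-fold), GPR137B, PLXNC1 and FCER2 (3.45-fold). NPW, MAP3K21, CSRP2, RASGRP1, GPR137B and PLXNC1 were named after their values were seen. Both comparisons share the high Myc arrays. Data simulated 100 times without effects gave 0 genes in either class, which is chance where nothing differs and tests no shared effect. Independent lists of these sizes would share 65.2 and 22.7 genes. With the high Myc arrays split between the comparisons in 6 ways, 47 to 119 genes were higher than in both others, with a median of 88.5 against 16.8 for independent lists, and 11 to 91 were lower, with a median of 27.5 against 5.70. The count of higher genes was 98, 104, 125 and 112 without high Myc replicates 3, 4 and 1 and low Myc replicate 1, 406 and 167 without low Myc replicates 2 and 3, and 136 and 140 without no Myc replicates 1 and 2. For the lower genes it was 255 without high Myc replicate 2, 44, 40, 30 and 25 without high Myc replicates 1, 3 and 4 and low Myc replicate 1, and 44 and 52 without no Myc replicates 1 and 2.

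The no Myc group, with the library labelled no Myc replicate 1 in it, set apart the most genes. From both other groups 1238 genes were higher in no Myc, led by IFI27, IFI44 and IFI44L, and 1888 were lower. Across the 19775 genes, which are not independent replicates, the difference of high from no Myc and that of low from no Myc had a correlation of 0.818. Data simulated without effects, which share the no Myc arrays in the same way, gave 0.632, and the covariance was 0.348 against 0.0307.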

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

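Of the tests reported here, that on the splits of the samples was planned, and those on mixing, on wrong labels and on immediate-early genes were chosen after the result was seen. Among the 4 high Myc arrays, 53 named genes and 34 list means were searched for an array far from the 3 others, by the gap to its nearest neighbour as a share of the whole range. Of these 87 values 13 had a gap beyond the critical value, where chance gives about 1 in 20 or 4.35 for normal values and the rate over all genes, 9.15%, would give 7.96, and 11 of the 13 were of replicate 2. Replicate 2 lay above the others for ADAMDEC1 (0.979), NRARP (0.965), ZC3H12C (0.96), PPEF1 (0.956), IL1R2 (0.936), CR2 (0.91), OTP (0.902), RCAN3 (0.878), ACKR3 (0.856) and CDK5R1 (0.845), and below them for OSBPL10 (0.911). Replicate 3 lay above the others for FABP5 (0.898) and for the mean of the plasma cell list (0.926). Over all genes the array apart was replicate 1, 2, 3 or 4 in 588, 512, 309 and 400 genes, so replicate 2 did not stand out by number there. It did stand out by correlation over all genes, with 0.982 with low Myc replicates 1 and 2 and 0.974 with low Myc replicate 3. With high Myc replicates 1, 3 and 4 it had 0.977, 0.986 and 0.980. The other high Myc arrays had at most 0.974 with any low Myc array.

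High Myc replicate 2 lay between the other high Myc arrays and the low Myc arrays for many genes that separated these groups. Mixing with low Myc cells or RNA would move every gene by about the same share. Of 45 genes at least 8-fold apart, 11 lay inside the range of the low Myc arrays and 4 inside that of the other high Myc arrays. A range can be wide, as TCEAL9, named after its value was seen, lay in the low Myc range at a share of 3.65%. By share, 11 of the 45 genes had moved by 80% or more and 11 by 20% or less. The shares ran from -25.6% to 122%, which argues against mixing as the whole cause. A wrong label of a low Myc array is argued against by MYC, which had moved by a share of 0.186 of the way to low Myc. A hypothesis that stays open and was not tested is that these cells may have been part of the way to the EBNA2-linked expression seen in low Myc. The mean log2 of that list was 9.68 on this array, 9.68 on the library labelled no Myc replicate 1 and 9.54 on no Myc replicate 2. Low Myc arrays read 10.09 to 10.31, so the level of this array was not particular to the way to low Myc.

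MYC in the library labelled no Myc replicate 1 (2803) was above every low Myc array and 6.74-fold above no Myc replicate 2. If high Myc cells or RNA had been mixed in, genes at least 8-fold higher in high Myc would carry the share that MYC shows, 19.1%, but the median share of 30 such genes was 0.329% (-3.54% to 3.64% apart from the outermost genes). A wrong label of a low Myc array would put genes at least 8-fold higher in low Myc at the low Myc level, but the median share of 30 such genes was 0.375%. Immediate-early genes, which respond within minutes to stimulation, were also higher in this library, with the median of 9 (0.73) at percentile 100 of 10000 random lists of like expression, though FOSB and IER3, named after their values were seen, were not higher. A candidate explanation is an immediate-early response in that library, which these values do not single out and which 1 array against 1 cannot separate from handling.

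The 712 genes between high and low Myc were set against other splits of the 7 arrays into 4 and 3. Of 35 splits, 1 gave as many genes, the real one. This is the smallest share that 35 splits can give, so the test cannot exclude chance beyond 1 in 35. The highest other count was 650, from the split that puts high Myc replicate 2 with the 3 low Myc arrays, which points to the structure of that array.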

How the results depend on the processing

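Leaving out 2 doubted libraries and array sets as a block were chosen after the data were seen, and all other alternatives were planned. No result changed direction while called. Of the results on gene lists 1851 stayed on their side of the threshold, 29 passed it and 58 fell short, and of those on named genes 3356, 3 and 517. Where the count of arrays fell, fewer degrees of freedom and a changed spread account for part of it by construction. Array sets were joined from deviations in these same values, so a block on them narrows the spread by construction, and its higher counts are no support. High Myc replicate 2 was alone in its set and drops out of the comparisons with that block. For all other shifts the cause was not tested.

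Genes called between high and low Myc were 143 at an adjusted p under 0.01, 328 with at least 2-fold, 2244 with array sets as a block, 1684 with array weights, 406 with only the 2 groups compared, 154 with the replicate number as a block, and 228 to 1204 with 1 array left out. Between high and no Myc they were 2353 with the 2 doubted libraries left out, 3048 at an adjusted p under 0.01, 2230 with at least 2-fold, and 2714 to 4868 with 1 array left out. For low and no Myc the same 4 settings gave 1976, 2188, 1913, and 1855 to 4381. Genes higher in high Myc than in both others were 148 with the doubted libraries left out, 69 at an adjusted p under 0.01, 99 with at least 2-fold, 578 with array sets, 542 with array weights, 65 with the replicate block, and 98 to 406 with 1 array left out. Genes lower in high Myc than in both others were 16 at an adjusted p under 0.01, 30 with at least 2-fold, 440 with array sets, 270 with array weights, 71 with the median of a gene's probe sets, 211 with quantile normalization repeated, 10 with the replicate block, and 25 to 255 with 1 array left out. Genes higher in low Myc than in both others were 158 with the doubted libraries left out, 17 at an adjusted p under 0.01, 51 with at least 2-fold, 433 with array sets, 301 with array weights, 176 with quantile normalization repeated, 25 with the replicate block and 20 to 280 with 1 array left out. Genes lower in low Myc than in both others were 32 at an adjusted p under 0.01, 85 with at least 2-fold, 560 with array sets, 291 with array weights, 96 with the median of a gene's probe sets, 62 with the replicate block and 63 to 302 with 1 array left out.

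The difference of MYC between high and low Myc was 2.72 with the replicate block (adjusted p = 0.119, over all alternatives 0.00134 to 0.119) and 2.47 to 2.87 with 1 array left out. Between low and no Myc it was 2.25 with the doubted libraries left out (adjusted p = 0.0087, over all alternatives 0.00842 to 0.698), and -0.50 to 2.25 with 1 array left out. Replicate numbers did not pair the arrays throughout, as 3 of 9 arrays went best with an array of their own number, with same-number correlations of deviations from -0.314 to 0.465. These 3 were the replicate 1 arrays of the groups, which went together at 0.251 to 0.465. High Myc replicate 4 had no array of its number in another group. Array sets were found from the values and are not a labelled batch. Within 2 of them, which held 1 array per group, MYC differed by 2.19 and 4.87 between high and no Myc, -0.40 and 1.79 between low and no Myc, and 2.58 and 3.08 between high and low Myc, and 2.61 between high and low Myc in another set without a no Myc array. A filter on dim genes left out 2534 genes, whose signal over background the arrays cannot judge here.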

Other observations

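The test on the MYC level and that on EBNA2-linked genes in low Myc, and all other overlaps given here, were chosen after the result was seen. Some genes were apart in low Myc from both other groups. Against both high and no Myc, 98 genes were higher in low Myc, led by CDK5R1 (13.7-fold), HNRNPLL (12.9-fold), OTP (12.1-fold), XCL1, a chemokine (log2 3.46), RCAN3 (10.5-fold), CR2 (10.4-fold), ZC3H12C (10.2-fold) and TIMP1 (9.32-fold), with the chemokine CCL20 (9.12-fold) and IL18R1, a receptor of interleukin 18 (9.07-fold), behind them, where each value is the smaller of the pair. The count was 20 without low Myc replicate 1, 30, 28 and 22 without high Myc replicates 1, 3 and 4, 34 and 37 without no Myc replicates 1 and 2, and 280 without high Myc replicate 2. Lower in low Myc than in both were 171 genes, led by JCHAIN (21.2-fold), OSBPL10 (15.6-fold), ALOX5 (13.7-fold), IQGAP2 (7.89-fold), SEL1L3 (7.19-fold), TBC1D9 (6.74-fold), CLMN (5.77-fold) and TCL1A, a lymphoid oncogene (5.62-fold). That count was 79 and 112 without low Myc replicates 1 and 3, 77, 73 and 63 without high Myc replicates 1, 3 and 4, 87 and 93 without no Myc replicates 1 and 2, and 302 without high Myc replicate 2. With the 2 doubted libraries left out, where low Myc exceeded the 1 no Myc array in MYC by 2.25 (adjusted p = 0.0087, over all alternatives 0.00842 to 0.698), the counts were 158 and 195. These folds and their order are not exact for CDK5R1, HNRNPLL, OTP, RCAN3, ZC3H12C, IL18R1, OSBPL10 and ALOX5, which read under a log2 of 5 on arrays of the dimmer group. IQGAP2, SEL1L3, CLMN, CCL20, IL18R1, STAT5A, CD83 and TNF, here or below, were named after their values were seen, and the no Myc side of each comparison includes the library labelled no Myc replicate 1. Independent lists of called genes would share 28.4 genes higher and 39.3 lower in low Myc than in both others, and data simulated without effects, which is chance where nothing differs, gave 0 and 0. Part of any excess can come from the low Myc arrays that both comparisons share.

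Among the genes lower in high Myc than in both others were HLA-DMB, HLA-DOA and HLA-DQB1 of 13 MHC class II genes (Fisher's exact test, two-sided, odds ratio 55.0, adjusted p = 0.00156). They were 0 without high Myc replicate 4, 2 without high Myc replicate 2 (adjusted p = 0.134), and HLA-DOA alone without high Myc replicate 1, low Myc replicate 1 or 2 or either no Myc array (adjusted p from 0.383). In the same class were CD83, FCER2 and TNF of 33 EBNA2-linked genes (adjusted p = 0.0138), with FCER2 alone without high Myc replicate 1, 3 or 4 or low Myc replicate 1 or 2, 2 genes without either no Myc array (adjusted p of 0.0833 and 0.116) and 19 without high Myc replicate 2. Among those lower in low Myc than in both others were BCL7A, CD27 and TCL1A of 17 germinal-centre genes (Fisher's exact test, adjusted p = 0.0134), with 0 without low Myc replicate 1, CD27 alone without high Myc replicate 1, 3 or 4, 2 without low Myc replicate 3 or either no Myc array (adjusted p of 0.0695 to 0.0966) and 5 without high Myc replicate 2. The p-values were adjusted over the 34 lists, and the genes of a list are not independent of each other. Each overlap was set against all 19775 genes, while a gene of these classes had to be called in 2 comparisons given above. All 13 MHC class II genes were called lower in high Myc than in no Myc, so their odds ratio in part repeats that fall. The other overlaps in part repeat such calls too.

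In low Myc 269 genes lay beyond both other groups, where 100 simulations that held each gene to a steady rise or fall with the MYC level of the arrays gave at most 2, but with the 2 doubted libraries left out the 353 genes stood against at most 10 with noise of single genes and, in 1 of 100 simulations with noise of whole arrays, 800, so a steady rise or fall with MYC alone was not excluded. Of 33 EBNA2-linked and B-cell activation genes, CD80, CDK5R1, CR2 and STAT5A were among the 98 genes higher in low Myc than in both others (odds ratio 28.8, Fisher's exact test, p = 2.08e-05, adjusted p = 0.000707). Leaving out high Myc replicate 1, 3 or 4, low Myc replicate 1 or either no Myc array left CR2 alone in that class (adjusted p = 1), while 8 members were in it without high Myc replicate 2 (5.07e-07) and 3 without low Myc replicate 2 or 3 (0.0298 and 0.0381). CD80 and CDK5R1 lost the call between low and no Myc in 7 and 4 of the 9 fits that left out 1 array (adjusted p up to 0.191 and 0.145), and the list was not called there by camera (0.168), with an estimated correlation (0.763) or by fry (0.434). The odds ratio was taken against all 19775 genes. Each of the 98 genes also had to be among the 252 genes lower in high Myc than in low Myc. Those 252 already held 8 members of the list, so the overlap in part repeats that difference and is no separate support for EBNA2 activity. That EBNA2 may have been more active in the low Myc cells is a hypothesis that these few list members cannot settle, as the labels state no estrogen treatment, EBNA2 itself was not analysed here and other differences in culture stay open.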
